A study of Mus musculus with 40 samples.

How the data were processed

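The series holds 40 samples, of which 14 were analysed: 12 repertoire libraries and 2 Hi-C libraries. The other 26, chromatin immunoprecipitation and 4C libraries, were not analysed here. Groups were taken from the sample labels: genotype (EACBE-/- or EACBE+/+) and receptor locus, with 2 libraries in each of the 6 repertoire groups and 1 Hi-C library per genotype. Per the labels' protocols, repertoire libraries were made by 5′ RACE with template switching from thymocyte RNA.

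The authors deposited each repertoire library as a table of whole-number counts, with V segments against J segments. The tool that assigned segments and whether a count is a read or a distinct receptor are not given in the sources used here. The deposited boundary lists give chromosome 14 intervals of 20000 bases with a boundary score each, called per library on mm10, per the file headers, which do not name the caller. Per the submitters' processing notes, the series used mm10, cutadapt 0.4.4, Bowtie2 2.20.8 and 2.3.4.3, bedtools 2.26.0, HiC-Pro 2.11.1 and Juicer 1.13.02, with no statement of which step each served. If counts are reads, an abundant receptor transcript weighs as much as many rare receptors, and amplification adds to the spread between libraries.

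All 189 segments in the tables were matched by symbol to a RefSeq annotation of GRCm38.p6, the assembly mm10 is built on. The replicates list different segments. In Tcra, 5 Trdv segments are listed in replicate 2 alone, with 2.01% of wild-type and 1.89% of EACBE-/- counts. In Trd, 66 V segments in wild type and 81 in EACBE-/- are listed in replicate 2 alone, and Trbv31 is listed in replicate 1 alone. These segments stayed in the library totals and in the sums per J segment, and out of the tests of V segments and V-J pairs.

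Counts were summed per segment and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with the table totals as library sizes, no TMM factors and filterByExpr at its defaults of 10 for the minimum count and 15 for the minimum total. The tests covered 106 Trav segments, 43 Traj segments, 2417 V-J pairs, 21 Trbv, 11 Trbj and 21 Trd V segments. P-values were adjusted by Benjamini-Hochberg within each of these, and the threshold was an adjusted p of 0.05. Traj segments were grouped as Traj61 to Traj42, Traj41 to Traj22 and Traj21 to Traj1. Trav genes were grouped as distal, central and proximal by splitting the 130 annotated Trav genes, in order, into 44, 43 and 43. Lists were tested with camera and fry from limma 3.58.1, camera with preset and with estimated correlation. Carry-over of wild-type reads into a block of V segments was tested in 3 ways, all added after the data were seen: by 3′ Traj share (Fisher's exact test), by the proportions of counts per segment (permutation test with fixed margins), and with each V-J pair counted once, by drawing as many pairs from another library 100000 times, weighted by its counts. The last was used to decide, since amplified reads are not independent, and a first bound for it, which set distances over unequal numbers of pairs against each other and was not met, was replaced after its value was seen by one at equal numbers of pairs (21 from each library, drawn 20000 times). Shares of lists were compared by a two-sided exact permutation test, and Wilson intervals are at 95%. For diversity, libraries were thinned to 10694 counts in 100 draws. A group at 0 was given a floor of 3 counts. Boundaries of the lists were called shared when they lay within 1 bin. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.

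The groups, tests, lists and the rule for named segments were chosen before the data were examined. Named segments were those past the threshold with non-overlapping libraries and the largest log2 changes, up to 15 V and 15 J in Tcra, up to 5 V in Trb and in Trd, 3 J in Trb and 6 V-J pairs; where fewer passed, the lowest p-values filled up to 5. Traj61, Traj58, Traj57, Traj56, Traj33, Traj18, Traj2, Trav1, Trav11, Trav17 and Trav21-dv12 were always named where listed, and Traj61 was not. Alternatives were TMM factors, DESeq2 1.42.0, no filter, each library left out, the replicate number as a block, other list bounds, each pair counted once, copies of V segments summed, no thinning and other overlaps of boundaries. Alternatives with segments of 1 replicate kept, totals over segments listed in both replicates, and the block with TMM factors were added after the data were seen.

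Each fit was tested on simulated counts with the means and totals of the real libraries. All segments of a fit were given 1 common dispersion, and libraries were drawn independently. Changes of 4-fold were recovered for 19% of changed Trav segments, 100% of Traj segments and 34.6% of V-J pairs, and 1.5-fold changes for 1.5%, 12.5% and 0%. In the simulation, the Tcra V and Trd V tests thus missed many changes of a size that the Traj test found. The real spread differs by segment, so these rates need not hold for a given segment.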

Results

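The T cell receptor alpha locus (Tcra) is assembled in developing T cells by joining a Trav segment to a Traj segment, under the control of the enhancer Ea, which lies downstream of the constant region gene Trac. The series title names a CTCF binding site at Ea, called EACBE in the labels, and asks for its role in Tcra rearrangement. CTCF is a DNA-binding protein that anchors chromatin loops. Thymus RNA of C57BL/6 mice with the site (EACBE+/+, wild type) and without it (EACBE-/-) was copied by 5′ RACE, which captures the V and J segments of receptor transcripts without V-specific primers. Counts per V-J pair were compared for Tcra, for the T cell receptor beta locus (Trb) and for the T cell receptor delta locus (Trd), which lies inside Tcra. Each of the 6 combinations of locus and genotype had 2 libraries. Hi-C, which measures contacts between stretches of chromatin, gave 1 list of insulation boundaries on chromosome 14 per genotype, from thymocytes of anti-CD3-treated Rag1-/- mice. The deleted site is not read by the receptor tables, so no value in them checks the genotype labels.

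Total counts in the Tcra tables were 10694 and 172388 in wild type, and 19085 and 163953 in EACBE-/-, for replicates 1 and 2 in turn. In Trb they were 11412 and 418135 in wild type and 20678 and 443589 in EACBE-/-. In Trd they were 1744 and 28093 in wild type and 5615 and 47158 in EACBE-/-. Replicate 2 was thus deeper than replicate 1 in both genotypes and its tables also listed other V segments. Nothing in the labels says that replicates came from separate mice, and p-values then measure only the spread between these libraries. Intervals and detection limits cover counting error only, because whether a count is a read or a distinct receptor is not given in the sources used here.

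The first comparison asked whether loss of EACBE moved the use of Traj segments, which run from Traj61 on the V side to Traj1 on the C side of the array. Segments at the 3′ end of the array were used less in EACBE-/- thymus. Traj4 took 2.299% ± 0.805 (SD, n = 2) of wild-type counts and 0.518% ± 0.103 of EACBE-/- counts, which is 4.44-fold lower, and Traj2, the last segment listed, was 6.36-fold lower, at 0.196% ± 0.0258 against 1.25% ± 0.829. In replicates 1 and 2, Traj4 took 1.73% and 2.87% in wild type and 0.445% and 0.590% in EACBE-/-, and Traj2 took 0.664% and 1.84% in wild type and 0.178% and 0.215% in EACBE-/-. Traj43, in the 5′ part, took 4.17% ± 0.163 in EACBE-/- (4.06% and 4.29%) and 2.49% ± 0.0507 in wild type (2.45% and 2.52%), which is 1.68-fold higher. The 3′ list (Traj21 to Traj1) as a whole held 23.98% and 29.6% of wild-type counts and 14.6% and 16.8% of EACBE-/- counts in replicates 1 and 2. Over the 106 Trav segments listed in both replicates, the replicate 2 values were 30.2% and 17.1%.

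Of 43 Traj segments tested, 12 changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 4 of them higher and 8 lower in EACBE-/-. All 8 that fell belong to the 3′ list. Traj2 fell by 2.70 on the log2 scale (SE 0.534, adjusted p = 0.0212 in edgeR), Traj4 by a log2 change of -2.15 (SE 0.304, adjusted p = 0.0149) and Traj5 by a log2 change of -1.95 (SE 0.299, adjusted p = 0.015). Smaller falls were measured for Traj9 (log2 change -1.17), Traj7 (-1.13), Traj13 (-0.82), Traj12 (-0.79) and Traj15 (-0.51). Traj38 rose by 0.76, Traj43 by 0.75, Traj44 by 0.73 and Traj47 by 0.49 on the log2 scale. These 12 segments had both libraries of one genotype above both of the other, as did 30 of the 43 tested, or 69.8%, where chance gives 33.3%. Traj2, Traj4, Traj5, Traj9, Traj12 and Traj43 passed whichever library was left out, though the log2 change of Traj2 was -1.71 without wild-type replicate 2 and -3.18 without wild-type replicate 1. The count was 6 without wild-type replicate 2 and 7 without EACBE-/- replicate 1: Traj7, Traj13, Traj38, Traj44, Traj15 and Traj47 lost their calls in both of these fits, and Traj47 in all 4. Traj7 also lost its call with TMM factors.

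All 14 members of the 3′ list had a lower share in EACBE-/- than in wild type in both replicate numbers. In this list 0 rose, 8 fell and 6 did not pass the test, and 9 fell when adjusted over the list alone. The 5′ list (Traj61 to Traj42) had 13 members listed, of which 3 rose and 10 did not pass, the count adjusted over the list alone being 3 as well. In both replicate numbers 10 were higher. Shares of a library have a fixed total, so a fall of the 3′ list by itself raises the shares of other segments. A rise of the 5′ list beyond that was not tested. In the middle list (Traj41 to Traj22), 1 of 16 rose, and 0 when adjusted over the list alone. The segments nearest the V side showed no change past the threshold: the log2 change was -0.08 for Traj58, 0.04 for Traj57 and 0.01 for Traj56, the last 2 of which turn negative with TMM scaling. Traj33, used by the invariant chain of mucosal-associated invariant T (MAIT) cells, had a log2 change of 0.37 (adjusted p = 0.222 in edgeR), and Traj18, used by invariant natural killer T cells, one of -0.37 (adjusted p = 0.117 in edgeR). Traj18 passed in DESeq2, with a log2 change of -0.47, and Traj33 passed without EACBE-/- replicate 2, with one of 0.58.

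As shares of all Tcra counts, the 5′ list held 30.5% ± 1.67 in wild type and 37.2% ± 1.83 in EACBE-/-, the middle list 42.7% ± 5.67 and 47.1% ± 3.42, and the 3′ list 26.8% ± 3.99 and 15.7% ± 1.59 (SD, n = 2 each). In replicates 1 and 2 the 5′ list held 29.3% and 31.7% in wild type and 35.9% and 38.5% in EACBE-/-, and the middle list 46.7% and 38.7% in wild type and 49.5% and 44.6% in EACBE-/-. With each V-J pair counted once, EACBE-/- minus wild type was 1.87 points for the 5′ list and -3.004 for the 3′ list. Of 4472 pairs of both-listed Trav segments with a count in any library, replicate 2 held 4377 in wild type and 4210 in EACBE-/-. Shares of pairs counted once are thus set in replicate 2 mostly by the number of segments in a list, and say little on their use. Without wild-type replicate 2 the middle list differed by 0.368 points. The 95% Wilson intervals of the 3′ share were 23.2 to 24.8% and 29.4 to 29.8% in the wild-type libraries, and 14.1 to 15.1% and 16.7 to 17.0% in the EACBE-/- libraries. With 2 libraries against 2, the two-sided exact permutation test cannot go below p = 0.333, the value it gave for the 5′ and 3′ lists. The competitive gene set test camera, with its preset correlation, placed the 3′ list lower (adjusted p = 6.94e-11, from limma) and the 5′ list higher (adjusted p = 0.0023) than the other Traj segments. For the 5′ list those others include the 3′ list, so its result is not separate from the 3′ fall. With an estimated correlation between segments the calls of these lists were lost, at adjusted p = 0.107 from limma for the 3′ and the 5′ list. For the middle list camera's adjusted p went from 0.0305 to 0.464. The test fry gave adjusted p = 0.0721 for the 3′ list, 0.0385 for the 5′ list and 0.280 for the middle list. With the array split at Traj32 instead, both parts passed in camera with estimated correlation (adjusted p = 0.0314) and in fry (adjusted p = 0.0128).

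**Figure D1:**
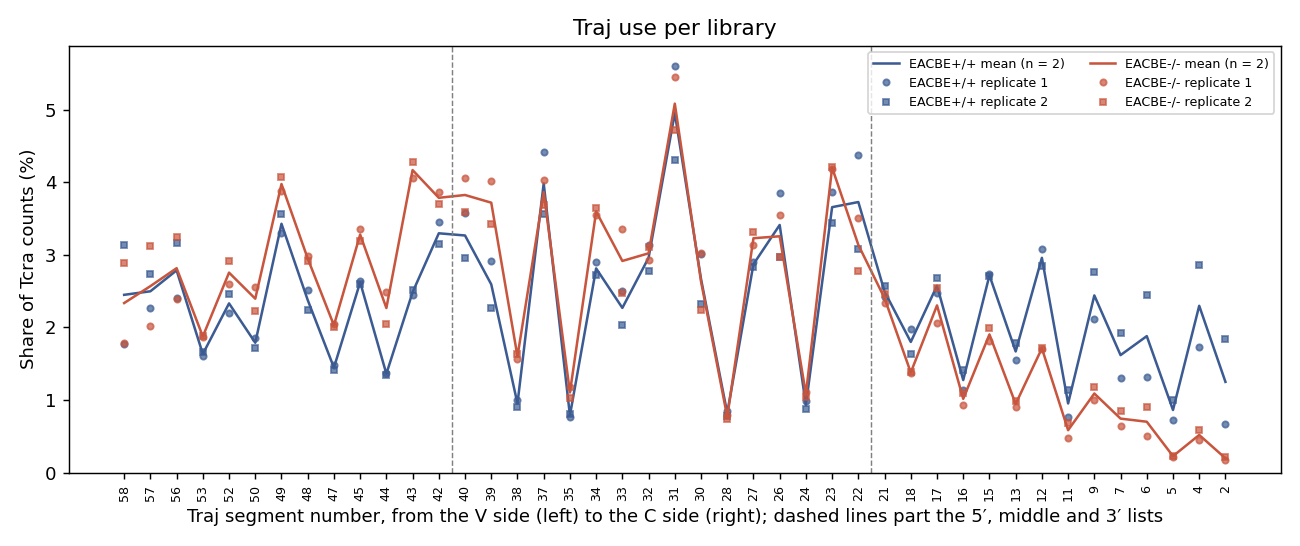
Share of Tcra counts (%) taken by each Traj segment, in order from the V side to the C side of the array; lines join the means of 2 libraries per genotype, and circles and squares are replicates 1 and 2. At the right end the EACBE-/- lines and points lie below the wild-type ones, as for Traj4 at 0.518% against 2.299%.

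The second comparison asked whether use of Trav segments moved along the V array, which spans chromosome 14 from Trav1 at 52427967 (mm10) toward the J array. Trav1 and Trav2, the segments farthest from the J array, were nearly lost from the EACBE-/- repertoire. Trav1, the outermost segment (52427967 to 52428876), took 1.134% ± 0.321 (SD, n = 2) of wild-type counts and 0.0135% ± 0.00424 of EACBE-/- counts, or 84.2-fold less. Trav2 (52567293 to 52568053) took 0.329% ± 0.0112 and 0.00628% ± 0.00147, or 52.3-fold less. Trav17, near the opposite end of the array (53806639 to 53807115), was also used less, at 1.16% ± 0.279 in wild type and 0.247% ± 0.0229 in EACBE-/-, which is 4.70-fold lower.

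Of 106 Trav segments tested, 6 changed at an adjusted p below 0.05 in edgeR's test, and all 6 were lower in EACBE-/-. These 6 had both libraries of one genotype above both of the other, as did 53 of the 106 tested, or 50.0%, where chance gives 33.3%. In both replicate numbers 41 segments were higher and 47 lower in EACBE-/-. The calls thus do not show that changes were few or only downward. Trav1 fell by 6.26 on the log2 scale (SE 0.526, adjusted p = 0.000714 in edgeR), from 97 and 2347 counts in the wild-type libraries to 2 and 27 in EACBE-/-. Trav2 fell by 5.58 (SE 0.907, adjusted p = 0.0221 in edgeR) and Trav17 fell by 2.22 (SE 0.379, adjusted p = 0.0221 in edgeR). Trav5-1 fell by 3.75, Trav7-1 fell by 2.87 and Trav7-2 fell by 1.63 on the log2 scale. Trav7-2, in the central part of the array (53390633 to 53391136), shares its number with the duplicated copy Trav7d-2. How the counting split reads of such copies is not given in the sources used here, so its value is uncertain. Trav7d-2 was lower as well, at 0.234% and 0.0702% in wild type and 0.0943% and 0.0336% in EACBE-/- in replicates 1 and 2. With copies summed all 6 calls were kept, which argues against a split between these copies as the source of the fall. Trav11, the invariant natural killer T cell V segment, had a log2 change of 0.40 (adjusted p = 0.593 in edgeR) and its copy Trav11d one of -0.19, with an SE of 2.54. Trav21-dv12, the proximal segment shared with Trd, had one of 0.41 (adjusted p = 0.589 in edgeR). Summing copies of duplicated segments raised the count of calls to 12 of 47, with 3 higher and 9 lower. Leaving out wild-type replicate 1 lowered the count to 3 and leaving out EACBE-/- replicate 1 lowered it to 2, and Trav1 passed whichever library was left out. Trav2 lost its call without either wild-type library, Trav5-1 without wild-type replicate 2 or EACBE-/- replicate 1, Trav17 without replicate 1 of either genotype, Trav7-2 without either EACBE-/- library and Trav7-1 without any of the 4, and Trav5-1 and Trav7-1 did not pass with TMM scaling, with segments of 1 replicate kept or with totals over segments listed in both replicates, each of which gave 4 calls. The log2 change of Trav5-1 was -5.52 without EACBE-/- replicate 2 and -3.18 without EACBE-/- replicate 1.

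By position, 4 of the 38 distal segments fell, as did 1 of 35 central and 1 of 33 proximal segments, and the counts adjusted over the list alone were the same, 4, 1 and 1. The other members did not pass. The distal list held 31.1% ± 2.33 of wild-type Trav counts and 29.5% ± 4.40 of EACBE-/- ones, the central list 21.4% ± 0.996 and 18.5% ± 1.33, and the proximal list 47.5% ± 1.33 and 52.0% ± 5.73 (SD, n = 2 each). In replicates 1 and 2 the distal list held 32.8% and 29.5% in wild type and 32.6% and 26.3% in EACBE-/-, the central list 20.7% and 22.1% against 19.5% and 17.6%, and the proximal list 46.5% and 48.4% against 48.0% and 56.1%. The distal difference of -1.67 points turned to 1.44 without EACBE-/- replicate 2 and to 1.63 with narrower bounds of the distal list. The central difference of -2.86 points turned to 1.36 with each V-J pair counted once, a measure that says little here because replicate 2 held nearly all pairs. The proximal difference of 4.53 points was 0.483 without EACBE-/- replicate 2. These differences did not hold up in camera (adjusted p = 0.374 for the distal and proximal lists and 0.749 for the central list, from limma). A block of 7 segments that precedes the first duplicated copy (Trav1, Trav2, Trav3-1, Trav5-1, Trav6-1, Trav7-1 and Trav6-2), chosen after its values were seen, held 2.67% and 3.58% of wild-type Trav counts and 0.11% and 0.41% of EACBE-/- ones in replicates 1 and 2. The 95% Wilson intervals were 2.38 to 2.99% and 3.49 to 3.67%, against 0.072 to 0.168% and 0.380 to 0.442%. Of its members, Trav3-1, Trav6-1 and Trav6-2 did not pass (adjusted p = 0.206, 0.336 and 0.593 in edgeR). Trav3-1 took 0.299% ± 0.0519 in wild type and 0.0357% ± 0.0357 in EACBE-/- (8.35-fold lower, SD, n = 2). Trav6-1 took 0.213% ± 0.0767 and 0.0217% ± 0.0306 (9.85-fold lower) and Trav6-2 0.207% ± 0.108 and 0.0912% ± 0.0919 (2.27-fold lower). Replicates 1 and 2 of EACBE-/- held 0.0105% and 0.0610% for Trav3-1, 0% and 0.0433% for Trav6-1, and 0.0262% and 0.156% for Trav6-2. These folds thus depend strongly on the library. In replicates 1 and 2, joins of the block had 3′ Traj segments in 35.1% and 44.5% of wild-type and 38.1% and 24.3% of EACBE-/- counts, and 5′ Traj segments in 3.86% and 6.92% of wild-type and 14.3% and 15.2% of EACBE-/- counts.

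**Figure D2:**
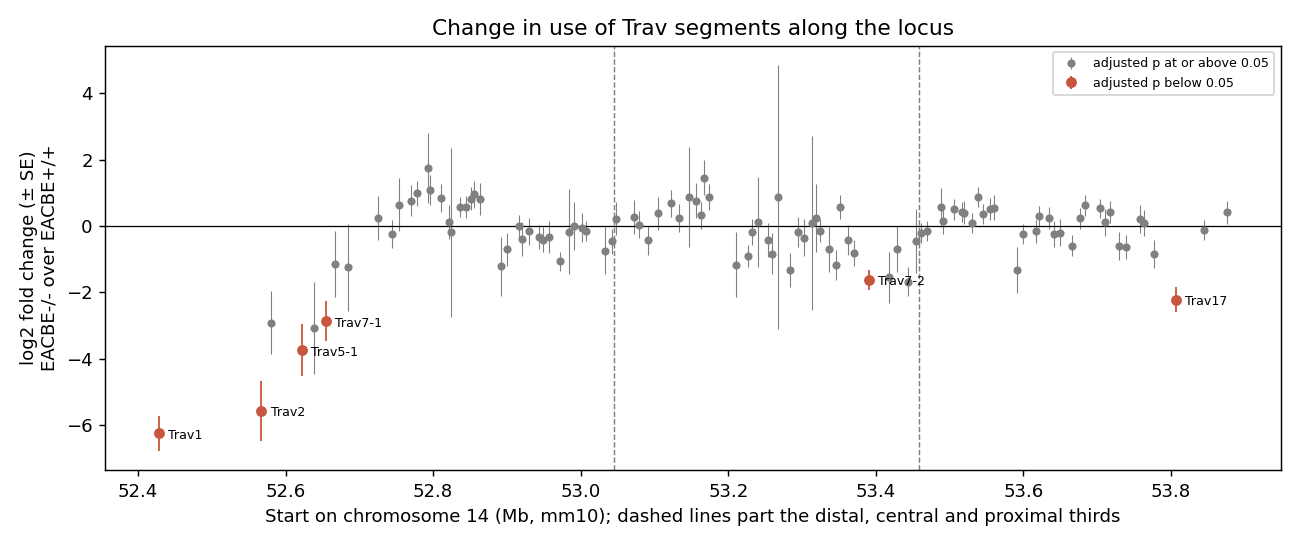
Log2 fold change of each Trav segment's use in EACBE-/- over wild type (± SE from edgeR, 2 libraries per genotype) against its start on chromosome 14 (Mb, mm10); red points passed an adjusted p of 0.05. The 4 red points at the left end lie between -2.87 and -6.26, and Trav17 at the right lies at -2.22.

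The joint use of V and J was compared next. Joins of distal Trav segments to 3′ Traj segments, the joins that span most of the locus, made up 11.6% and 12.1% of wild-type counts and 6.39% and 6.11% of EACBE-/- counts in replicates 1 and 2. Joins of distal Trav to 5′ Traj segments were higher in EACBE-/-, at 7.84% ± 1.25 against 5.48% ± 0.128 (SD, n = 2), and by replicate number 8.73% against 5.57% and 6.96% against 5.39%. Joins of proximal Trav to 5′ Traj segments took 22.9% ± 2.57 in EACBE-/- (21.1% and 24.8%) and 20.2% ± 0.269 in wild type (20.0% and 20.4%), and joins of proximal Trav to 3′ Traj segments took 5.85% ± 1.59 and 6.87% ± 2.14, which differed by less than the spread between replicates. The exact permutation test could not go below p = 0.333 for any of the 4 classes. With each V-J pair counted once, EACBE-/- minus wild type turned from 2.74 to -0.101 points for proximal Trav with 5′ Traj segments. It went from 2.36 to 0.514 for distal Trav with 5′ and from -5.61 to -2.05 for distal Trav with 3′ Traj segments. Nearly all pairs were seen in replicate 2, so this measure cannot show whether the differences rest on a few pairs. Class shares also have a fixed total, so rises are not separate from falls. Without EACBE-/- replicate 2 the difference for proximal Trav with 5′ Traj segments was 0.919 points, and without EACBE-/- replicate 1 it was 4.56, and that for distal Trav with 5′ Traj segments 1.48.

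Among 2417 V-J pairs tested, 81 changed at an adjusted p below 0.05 in edgeR's test, 9 higher and 72 lower in EACBE-/-. Of the pairs that fell, 20 used Trav1, 16 used Traj4 and 8 used Traj2. Falls of Trav1 pairs are not separate from that of Trav1 itself, which had 2 and 27 counts in EACBE-/-. The pair of Trav1 with Traj26 had 10 and 146 counts in wild type and 0 in both EACBE-/- libraries, which with counts pooled per genotype, and a floor of 3 counts over the EACBE-/- group, is at least 52.0-fold lower. On the same floor, Trav1 with Traj32, at 9 and 102 counts in wild type, was at least 37.0-fold lower. Trav1 had 4 and 124 wild-type counts with Traj12, 3 and 118 with Traj15, 2 and 99 with Traj30 and 2 and 62 with Traj16, against 0 in both EACBE-/- libraries, and 0 counts allow a share of up to 0.00164% for each pair. The pairs that rose included 4 of Trav14d-1 and 3 of Trav7d-4, but 0 pairs were called higher in DESeq2, 1 with segments of 1 replicate kept, 1 without EACBE-/- replicate 1 and 2 without EACBE-/- replicate 2. The count of pairs rested on the deep libraries: it was 0 without wild-type replicate 2, 8 without EACBE-/- replicate 2, 46 without EACBE-/- replicate 1 and 150 without wild-type replicate 1. DESeq2 called 18 pairs, Trav1 with Traj16 not among them. With a library left out, Trav1 with Traj16 was tested in 2 of the 4 fits and the other named pairs in 3. Without EACBE-/- replicate 2, Trav1 with Traj32, Traj12, Traj15 or Traj30 did not pass.

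Thinned to 10694 counts, wild-type libraries showed 2940 ± 131 different V-J pairs and EACBE-/- libraries 2711 ± 35.5 (SD, n = 2), and Shannon entropy was 10.99 ± 0.0754 and 10.82 ± 0.0117 bits. Both EACBE-/- libraries lay below both wild-type libraries (exact permutation p = 0.333, the smallest possible with n = 2). The difference of -229 pairs turned to 61.5 without thinning, and was -136 without wild-type replicate 2. Pairs that other T cell types of the thymus use were rare. Trav11 of any copy with Traj18, the pair of invariant natural killer T cells, took 0.112% (95% Wilson interval 0.0642 to 0.196%) and 0.0435% (0.0347 to 0.0545%) of wild-type counts, and 0.0891% (0.0556 to 0.143%) and 0.0433% (0.0343 to 0.0546%) of EACBE-/- counts, so no difference was detectable at this depth. Trav1 with Traj33, the pair of MAIT cells, had 4 and 44 counts in wild type, or 0.0374% (0.0146 to 0.0961%) and 0.0255% (0.019 to 0.0343%). It had 0 counts in either EACBE-/- library, which allows shares of up to 0.0157% and 0.00183%. Trav1 as a whole had 2 and 27 counts there, so the 0 adds nothing to the fall of Trav1 and does not measure MAIT cells. A V-J pair alone does not show the invariant junction of either cell type.

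Trb, on chromosome 6, served as the comparison locus away from the deleted site. Its V and J use differed little between genotypes. The V segments with the lowest p were Trbv30, at 0.326% ± 0.0394 in wild type and 0.27% ± 0.0124 in EACBE-/- (log2 change -0.30, SE 0.196), then Trbv2 (0.15), Trbv4 (0.15), Trbv26 (-0.10) and Trbv20 (-0.10), each with adjusted p = 0.97 in edgeR. Of 21 Trbv segments tested, 0 passed in edgeR and 0 in DESeq2, and 0 had an unadjusted p below 0.05 by either. Of 11 Trbj segments, 0 passed by either tool; Trbj1-5 alone had an unadjusted p below 0.05 in edgeR (log2 change 0.13, SE 0.0399, adjusted p = 0.252), and DESeq2 gave 0. Trbj1-4 had a log2 change of 0.15 and Trbj2-4 one of -0.05. The Trbj1 cluster held 30.4% ± 2.05 of wild-type counts and 31.98% ± 0.660 of EACBE-/- counts (SD, n = 2; by replicate number 31.9% and 29.0% against 32.4% and 31.5%), a difference within the spread between replicates. In simulated Trb counts of the same depth, with 1 common dispersion, 4-fold changes were recovered for 100% of changed V segments and 1.5-fold changes for 22.5%.

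In Trd, the V segments Trdv1 and Trdv2-2 had lower shares in EACBE-/- thymus. Trdv1 (chromosome 14, 53881612 to 53882217) took 11.4% ± 0.229 (SD, n = 2) of wild-type counts and 4.05% ± 0.367 of EACBE-/- counts, and Trdv2-2 (53960993 to 53961602) took 29.2% ± 6.10 and 16.7% ± 1.41, or 33.5% and 24.9% against 17.6% and 15.7% in replicates 1 and 2. Trdv5 (54148662 to 54149201), which lies on the far side of the Trd constant region and joins by inversion, took 12.6% ± 0.0382 in wild type (12.6% and 12.7%) and 19.0% ± 2.91 in EACBE-/- (16.9% and 21.05%). Without Trdv1 and Trdv2-2 in the total, a check added after the values were seen, Trdv5 held 21.4% ± 2.22 and 23.9% ± 3.13, a difference within the spread between replicates. Trav15-1-dv6-1 took 6.82% ± 1.20 and 9.64% ± 1.52, and Trav15-2-dv6-2, which like it has near-identical copies, took 11.997% ± 1.56 and 14.9% ± 0.826. Lower shares of Trdv1 and Trdv2-2 by themselves raise those of other segments. A rise of either Trav15 segment beyond that was not tested.

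None of the 21 Trd V segments passed an adjusted p of 0.05: edgeR and DESeq2 each called 0, with 3 and 1 at an unadjusted p below 0.05. The log2 change of Trdv1 was -1.496 (SE 0.21, adjusted p = 0.0609 in edgeR), that of Trdv2-2 was -0.81 (adjusted p = 0.218) and that of Trdv5 was 0.59 (adjusted p = 0.248). With totals taken over the V segments listed in both replicates, Trdv1 alone passed. The 95% Wilson intervals of the Trdv1 share were 10.2 to 13.2% and 10.9 to 11.6% in the wild-type libraries and 3.81 to 4.87% and 3.62 to 3.97% in the EACBE-/- libraries. Trdv segments together, as against V segments shared with Tcra, made up 58.2% and 49.1% of wild-type counts and 39.3% and 41.0% of EACBE-/- counts in replicates 1 and 2, and the difference was -8.93 points without wild-type replicate 1, against -13.5 with all libraries. Trdj2 took 0.953% ± 0.051 of wild-type and 0.852% ± 0.0293 of EACBE-/- counts (SD, n = 2), and the other counts had Trdj1. The exact permutation test allowed no p below 0.333 for these shares. At this depth, with 1 common dispersion, simulated 4-fold changes in Trd V use were recovered for 0% of changed segments. The real spread differed by segment, with an SE of 0.21 for Trdv1 and 2.22 for Trav14d-3-dv8, so this rate need not hold for each.

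**Figure D3:**
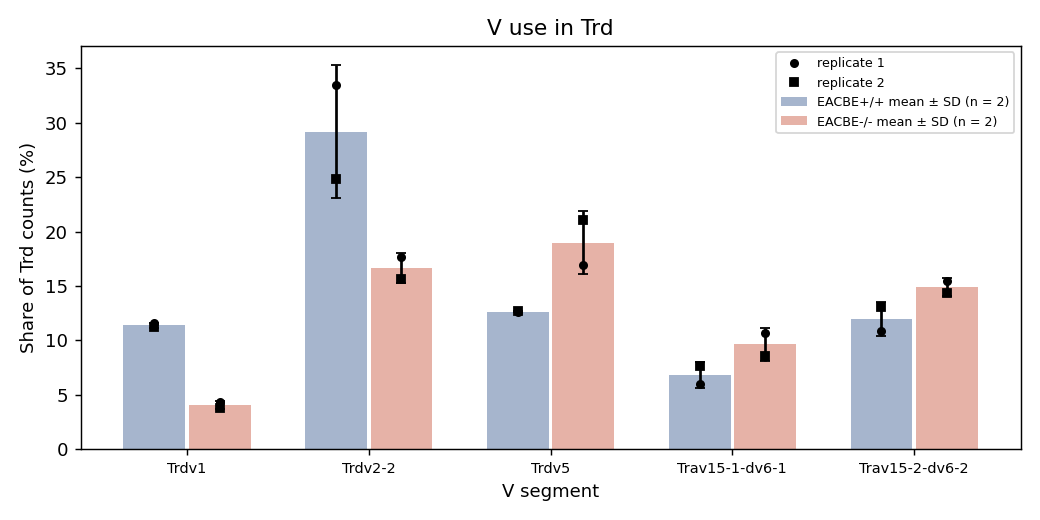
Share of Trd counts (%) for the 5 V segments with the lowest p; bars are means of 2 libraries per genotype with SD, and circles and squares are replicates 1 and 2. For Trdv1 both EACBE-/- libraries (4.31% and 3.79%) lie below both wild-type libraries (11.6% and 11.3%).

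Hi-C insulation boundaries asked whether chromatin domains around the locus differed. There was 1 library per genotype, so no difference has a replicate check. Both lists kept a boundary at each end of the Tcra-Tcrd locus. Just outside Trav1, the bin from 52360001 to 52380000 (mm10) was a boundary in both, with scores of 0.943 in wild type and 1.08 in EACBE-/-. Beyond Trac, the nearest boundary lay at 54240001 to 54260000 in wild type (score 1.30) and 1 bin farther, at 54260001 to 54280000, in EACBE-/- (score 1.24). A score is the authors' own boundary strength.

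Inside the locus (52427967 to 54224198), wild type had 5 boundaries and EACBE-/- 3. The bin with Trav5-1 and Trav6-1 (52620001 to 52640000) was a boundary in both, with a score of 0.633 in wild type (percentile 64.8 of its list) and 0.337 in EACBE-/- (percentile 9.01 of its list). The bin with Trdv4 (54060001 to 54080000) also occurred in both, with scores of 0.437 and 0.632. A boundary at Trav4-4-dv10 in wild type (53680001 to 53700000, score 0.588) had an EACBE-/- counterpart 1 bin away, at Trav5-4, Trav6-7-dv9 and Trav7-6 (53700001 to 53720000, score 0.517). Boundaries at Trav17 (53800001 to 53820000) and at Trav19 (53840001 to 53860000) were listed in wild type alone, both with a score of 0.324 (percentile 8.88), 5 and 7 bins from the nearest EACBE-/- boundary. The lowest score in the wild-type list was 0.3005. In that list of 400, 60 boundaries had the same score as the one before them. Whether Trav17 and Trav19 mark separate boundary calls is therefore not known.

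On the whole of chromosome 14, the wild-type list held 400 boundaries and the EACBE-/- list 533. Within 1 bin of 20000 bases, 59.5% of the wild-type boundaries (238; 95% Wilson interval 54.6 to 64.2%) had an EACBE-/- counterpart, and 44.5% of the EACBE-/- ones (237; 40.3 to 48.7%) a wild-type one, where random positions gave 24.2% and 18.7%. Median scores were 0.491 and 0.481. Boundaries without a counterpart were weaker, with median scores of 0.399 against 0.634 in wild type and 0.412 against 0.683 in EACBE-/-. The depth of the Hi-C libraries is unknown, and the lengths of the lists can differ with it.

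**Figure D4:**
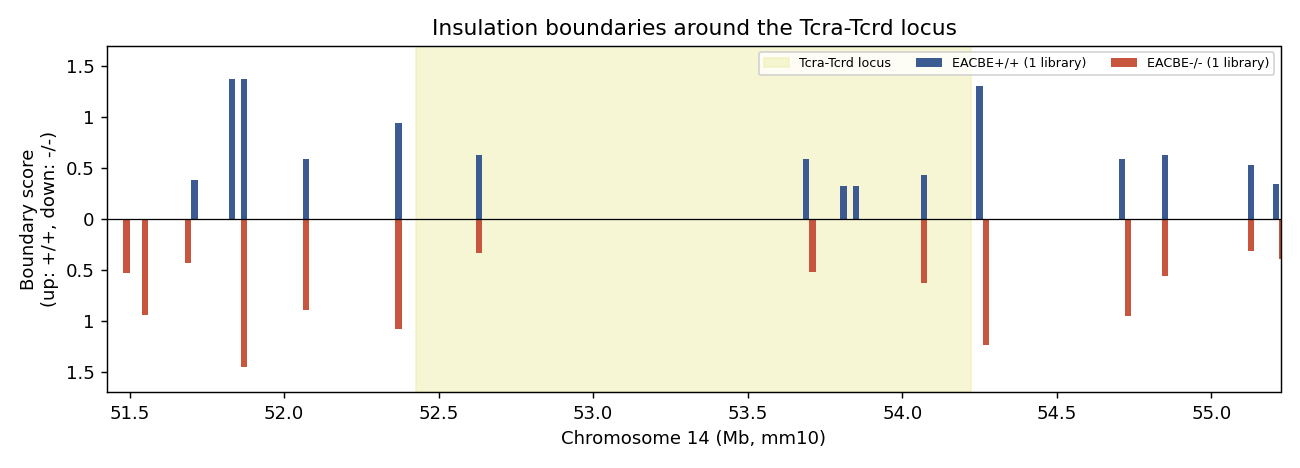
Insulation boundaries within 1000000 bases of the Tcra-Tcrd locus on chromosome 14 (Mb, mm10), as deposited boundary scores, wild type drawn upward and EACBE-/- downward, 1 library each; the shaded span is the locus. The wild-type boundaries at Trav17 and Trav19 (score 0.324) have no EACBE-/- boundary opposite them.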

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

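V segments listed in a single replicate number take no part in the comparisons of V segments and V-J pairs. Their counts are in the sums per J segment. Many of those in Trd had few counts or 0, such as Trav7-3 with 0 in both replicate 2 libraries. The shares given next stand above the limit that a count of 0 allows. Trdv1 joined to a Traj segment made up 1.53% of the wild-type and 1.23% of the EACBE-/- counts in replicate 2 of Tcra. Trbv31 made up 4.85% of the wild-type and 4.26% of the EACBE-/- counts in replicate 1 of Trb. V segments listed in replicate 2 of Trd alone made up 7.70% of the wild-type and 9.49% of the EACBE-/- counts, and Trav15n-1 had the highest share of them, at 3.49% and 4.50%.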

How the results depend on the processing

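The alternatives of the block with TMM factors, of segments listed in 1 replicate and of totals over both-listed segments were chosen after the data were seen, and the cause of a change was not tested unless given. Among 24 called segments and pairs that are named, 192 of 233 values under alternatives kept direction and call, 41 lost the call and 0 reversed. Fits in which a named pair was not tested are not among these values. Among the named segments that were not called, 178 of 215 values stayed so in the same direction, 19 passed the threshold and 18 reversed. Fewer pairs enter the test when a deep library is left out: 880 without wild-type replicate 2 and 913 without EACBE-/- replicate 2, of 2417.

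Calls of Trav segments went from 6 to 12 with copies summed, which also leaves fewer segments to adjust over. Calls of V-J pairs went from 81 to 18 in DESeq2, to 129 with no filter and to 29 with segments of 1 replicate kept. In Trd, totals over segments listed in both replicates gave 1 call. Leaving out each library gave 2 to 4 Trav calls, 6 to 13 Traj calls and 0 to 150 pair calls, and 0 in Trb and Trd.

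With the replicate number as a block, calls were 49 for Trav (23 higher and 26 lower in EACBE-/-), 32 for Traj (19 and 13), 716 for pairs (353 and 363), 1 for Trbv, 2 for Trbj and 3 for Trd V, and with TMM factors as well 51, 33, 792, 1, 2 and 2. Libraries with the same number deviated together (correlations 0.832 for Trav, 0.787 for Traj, 0.828 for Trbv, 0.903 for Trbj and 0.903 for Trd V). No label pairs the libraries and there are 2 pairs, so pairing is not established; the number goes with depth and listed segments in both genotypes, so a shared batch stays open. Under the block the log2 change of Trav11d reversed to 0.43, and to 0.48 with TMM factors, and that of Traj56 to -0.0437 with TMM factors.

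With estimated correlation, camera's adjusted p (limma) was 0.107 for the 3′ and the 5′ Traj list and 0.464 for the middle one. Leaving out a library gave adjusted p in camera of 0.00394 to 0.192 for the middle list. With each pair counted once, EACBE-/- minus wild type was 1.87 points for the 5′ and -3.004 for the 3′ Traj list. It was 1.36 for the central and 0.290 for the proximal Trav list. For joins it was -0.101 for proximal V with 5′ J, 0.514 for distal V with 5′ J and -2.05 for distal V with 3′ J. In replicate 2 this measure is nearly saturated, with 4377 of 4472 pairs seen in wild type and 4210 in EACBE-/-, so smaller or turned differences say little on use. Split at Traj32, the 5′ part differed by 10.7 points. With V copies left out, the differences were -30.7 for distal, -1.28 for central and 31.98 for proximal Trav, over 7, 1 and 4 segments, the 7 being the block before the duplicated copies. Without thinning, pairs seen differed by 61.5. Trav1 with Traj33 differed by -0.0374 to -0.0255 points when each library was left out.

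Traj57 reversed to -0.003 with TMM factors and -0.0775 in DESeq2, and Traj56 to -0.0356 and -0.11. Leaving out each library gave log2 changes from -0.48 to 0.42 for Traj58, -0.32 to 0.31 for Traj57, -0.23 to 0.23 for Traj56, -2.27 to 3.48 for Trav11d, -0.194 to 0.008 for Trbv26 and -0.294 to 0.162 for Trbv20.

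Of wild-type boundaries, 33.0% had an EACBE-/- boundary in the same bin, 69.5% within 2 bins and 74.0% when both lists kept the boundaries at or above their median score; of EACBE-/- boundaries, 24.8%, 52.3% and 55.8%.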

Other observations

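Of the tests given here, that of a few V-J pairs was stated before its value was seen, apart from the count of V segments given with it; the others were chosen after the results were seen. Use of 3′ Traj segments was also measured by the position of the V segment joined. Joins of distal Trav segments had 3′ Traj segments in 38.7% ± 4.75 (SD, n = 2) of wild-type and 21.6% ± 2.84 of EACBE-/- counts, and joins of central segments in 38.0% ± 5.48 and 19.8% ± 2.63. Joins of proximal segments had them in 14.6% ± 4.36 and 11.3% ± 2.00, a difference within the spread between replicates. The mean Traj number went from 26.3 to 31.8 for distal and from 26.6 to 33.0 for central segments, against 36.7 and 37.6 for proximal ones. Whether the positions differ in their change was not tested.

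Of the 7 V segments before the duplicated copies, Trav1, Trav2, Trav5-1 and Trav7-1 fell in EACBE-/-, and Trav3-1, Trav6-1 and Trav6-2 did not pass, at 8.35-, 9.85- and 2.27-fold lower shares; depth is argued against, since the wild-type library with the smallest total held 2.67%. With each V-J pair of the block counted once, the pairs of EACBE-/- replicate 1 (n = 21 pairs) and replicate 2 (n = 189 pairs) fell on other segments than pairs drawn from wild-type replicate 2 (resampling p = 3e-05 and 1e-05, the latter the smallest that 100000 draws can give), which was not detected for wild-type replicate 1 (n = 131 pairs, resampling p = 0.533). The same test also separated the EACBE-/- libraries from each other, with 34.6% of pairs on other segments against a drawn median of 17.5%. Its result alone thus does not set the genotypes apart. With 21 pairs from each library, a median of 46.2% of the pairs of either EACBE-/- library lay on other segments than in wild-type replicate 2. This was 19.7% for wild-type replicate 1, 34.4% between the EACBE-/- libraries and 18.8% with no difference. The distance to wild type was thus larger than the distances within a genotype, by a bound set after a first one was not met. EACBE-/- replicate 1 held 21 pairs in all, so its distances are single values without a spread. For EACBE-/- replicate 2 the 5th percentile of the distance to wild type was 35.8%, close to the distance between the EACBE-/- libraries. The order of the distances goes against wild-type reads carried over as the source of all counts of the block, but does not exclude it. For Trav1 and Trav2, neither carry-over nor counts of other segments assigned to them can be told apart from true use: 39 counts in replicate 2 had a 3′ Traj share of 25.6%, against 46.1% in wild type (Fisher's exact p = 0.0142, over counts that may not be independent) and 16.8% for all other V segments (Fisher's exact p = 0.138), and replicate 1 had 3 counts. Loss of EACBE remains open. So do a germline lack of Trav1, Trav2 or more of the block, and another germline difference between the mice at this end. Counts of similar segments assigned to the other members of the block were not tested.

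The lower 3′ Traj share in EACBE-/- may follow from loss of the site, as a hypothesis. It was present within each replicate number, at -9.38 and -12.8 points, which argues against the difference between the replicates. With wild-type V use, 82.8% of the gap was left in replicate 1 and 86.5% in replicate 2, so the change in V use is not its whole cause. With each pair counted once the difference was -3.004 points, which lies within the spread between replicates. The once-counted shares were 30.8% in wild type and 26.4% in EACBE-/- in replicate 1, and 32.9% and 31.4% in replicate 2. Replicate 2 held nearly all pairs, so there this measure cannot decide. Of 84 V segments with at least 20 counts in every library, which leaves out the block before the duplicated copies, 69 had a lower 3′ share in both replicate numbers. Independent segments would give 21 by chance, but these come from the same libraries and may move together, so 21 is no null for them. A higher share in both was seen for 3, the proximal segments Trav17, Trav3-3 and Trav5-4. The fall was thus spread over many V segments, which argues against a few pairs.

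Changes in V use may be shared by neighbours. With copies summed, the log2 change of each of 47 segments correlated with that of the next along the array (r = 0.830, Spearman's rho = 0.698, each with one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Without the 7 outermost segments, r was 0.435 over 40 segments (permutation p = 0.00169). This correlation is across segments, which are not independent replicates, and segments alike in sequence lie near each other, so shared reads stay open.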
